A study of Mus musculus with 8 samples.

How the data were processed

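RNA was sequenced in 8 libraries of primary mouse cells from inguinal white adipose tissue (iWAT), the subcutaneous fat pad of the groin. Per the labels' protocols, cells of the stromal-vascular fraction, which holds the fat cell precursors, were grown to confluence and differentiated for 2 days in 1 µM rosiglitazone (an agonist of the fat cell regulator PPARγ), 0.5 mM IBMX (a phosphodiesterase inhibitor), 1 µM dexamethasone and 870 nM insulin, and then kept in rosiglitazone and insulin. On day 3 to 4 of differentiation they received an adenovirus for green fluorescent protein (GFP) or for PSAP, at a multiplicity of infection of 100. The medium was replaced after 24 h and the cells were collected at 72 h. Strand-specific mRNA libraries were made from 200 ng of total RNA. Groups and replicate numbers were taken from the sample titles, 4 libraries with GFP and 4 with PSAP. No label says whether the 4 libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical. No label says which species the PSAP sequence in the virus came from.

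The authors deposited transcript abundances in TPM for each gene symbol and library, which are scaled so that each library sums to 1000000. Reads were aligned with STAR to the mouse build mm10, per the submitters' processing notes; the versions, the gene annotation and the counting step are not given in the sources used here. TPM divides by transcript length and by the library's own total, so it keeps no depth: the reads behind each library are unknown, and no counting interval was computed. Because every library has the same total, a rise of very abundant transcripts lowers the value of the others. The kit marks the strand, but whether the counting used it is not given in the sources used here, so genes overlapped by an antisense gene are uncertain. Near-identical copies that share reads, such as Ifit3 with Ifit3b and the H2 class I genes among themselves, are uncertain too.

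The authors deposited a table of the PSAP against GFP comparison, made by the authors with DESeq per the submitters' processing notes. It holds 18383 genes, 16242 of them with an adjusted p. Per the file headers it gives a mean normalised count, a signal averaged over the compared libraries. Per the file headers it also gives a log2 fold change and its standard error on the log2 scale. The deposited test statistic is a Wald score, and the deposited significance is a p-value and an adjusted p-value. The signal column summed to 35786500, which is the mean size of a library after the authors' scaling and not the depth of any library. Of these genes, 444 had no entry of the same symbol among the TPM values. Values from it are named as the authors' and were set beside the TPM fit, and no test was run on it.

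Symbols were matched without regard to case, and 23574 had a match in the mouse gene names used here while 63 had none. Gene coordinates come from the GENCODE annotation of mm10 and are 1-based. The analysis used log2(TPM + 1) and the 11984 genes with a mean of at least 1 TPM over the 8 libraries. Differences were tested with limma 3.58.1 in R 4.3.3, as PSAP minus GFP with no covariate and an intensity trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Folds are on the log2(TPM + 1) scale, which understates the change of low genes. Psap and Ucp1 also had an exact two-sided permutation test over the 70 relabellings of 4 against 4, which cannot give a p below 0.0286.

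Before the data were examined, 21 gene lists were fixed from textbook pathways and cell markers. For each list the members higher, lower and not passing were counted, over all genes and adjusted over the list alone. The 20 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, whereas fry asks whether the members move one way on balance. The score of a list in a library is the mean over its members of log2(TPM + 1) after subtracting each gene's mean over the 8 libraries. The named genes were also fixed by rule: Psap, Ucp1, Cidea, Ppargc1a and Dio2; the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, without gene models, pseudogenes and unmatched symbols; and the 4 members of each list with the smallest p. A gene named outside this rule is said to be chosen after its values were seen.

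The alternatives were pseudocounts of 0.1 and 5, filters at 0.1 and 5 TPM and none, median-of-ratios and quantile scaling, TPM rescaled without Psap, eBayes without trend and with robust variance, array weights, the replicate number as a block, each of the 8 libraries left out in turn, an adjusted p under 0.01, a fold of at least 1.5, and the authors' comparison. After the data were seen, the split of replicates 1 and 2 from replicates 3 and 4 was added as a covariate and as separate fits of each part. On simulated data built from these genes and their spread, the same limma fit recovered 23.9% of genes changed by 0.32 on the log2 scale, 67.2% of genes changed 1.5-fold and 93.9% of genes changed 2-fold, with 4 calls among the unchanged genes of the 11984. Only 67, 67 and 66 genes were changed in that simulation, whereas 56.8% of genes were called in the data. The p-value cut-off was therefore stricter in the simulation, and its rates and 4 calls do not describe the fit of the data. A gene that did not pass can still have changed by 0.32 or more. On simulated lists of 25 genes, camera called the shifted list and 0 of the 20 unshifted ones. The simulated genes varied independently, whereas the estimated correlation in the list of interferon genes was 0.845. The simulated lists therefore say nothing on false calls in correlated lists. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.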

Results

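The RNA of primary mouse iWAT cells was profiled in 8 libraries, 4 made 72 h after an adenovirus for GFP and 4 made 72 h after an adenovirus for PSAP. Prosaposin, the product of Psap, is cut in the lysosome into the saposins, which help enzymes break down sphingolipids, and it is also secreted. The comparison asks how the RNA levels of differentiating fat cells differ between the PSAP virus and the GFP control virus. Between 15667 and 16394 genes had a value above 0 in a library, and the read depth behind the values is unknown. Over the genes tested, which are not independent replicates, libraries of the same group correlated with a Pearson r of at least 0.991 for GFP and 0.993 for PSAP, and the highest r between groups was 0.972. The first principal component held 79.0% of the variance and separated the groups, and the second held 7.50% and separated replicates 1 and 2 from replicates 3 and 4 in both groups. Fabp4, the fat cell fatty acid binding protein, took 7.37% to 10.1% of the TPM of a library. The ribosomal precursor Rn45s took 0.514%, 0.420% and 0.265% in GFP replicates 1, 2 and 3, and between 0.163% and 0.193% in the other libraries.

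The transgene was examined first, as a check of the labels. Psap (chromosome 10, 60277627 to 60302597 on mm10, protein-coding) stood at 1048 ± 50.8 TPM in the GFP libraries and 1144 ± 86.5 TPM in the PSAP libraries (SD, n = 4). GFP replicates 1 to 4 held 1017, 993, 1093 and 1089 TPM, and PSAP replicates 1 to 4 held 1096, 1095, 1273 and 1111 TPM. Every PSAP library thus lay above every GFP library, by 1.09-fold on average, and the exact permutation test gave p = 0.0286, the smallest that 70 relabellings can give. Such a separation is not particular to Psap, since 51.8% of the genes tested separated the groups. In the limma fit the log2 difference of 0.12 ± 0.07 (SE) did not pass, with an adjusted p of 0.152. The authors' deposited table gives a log2 fold change of 0.17 ± 0.05 (SE) with an adjusted p of 0.00454. The call changed with the setting. Median-of-ratios scaling gave 0.17 with an adjusted p of 0.0283, and the replicate number as a block gave 0.12 with 0.0424. Quantile scaling gave 0.05 with an adjusted p of 0.535, and the fit without PSAP replicate 3 gave 0.07 with 0.362. How much of the transgene's RNA the Psap row can hold is unknown, since the species of the PSAP sequence is not stated.

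**Figure D1:**
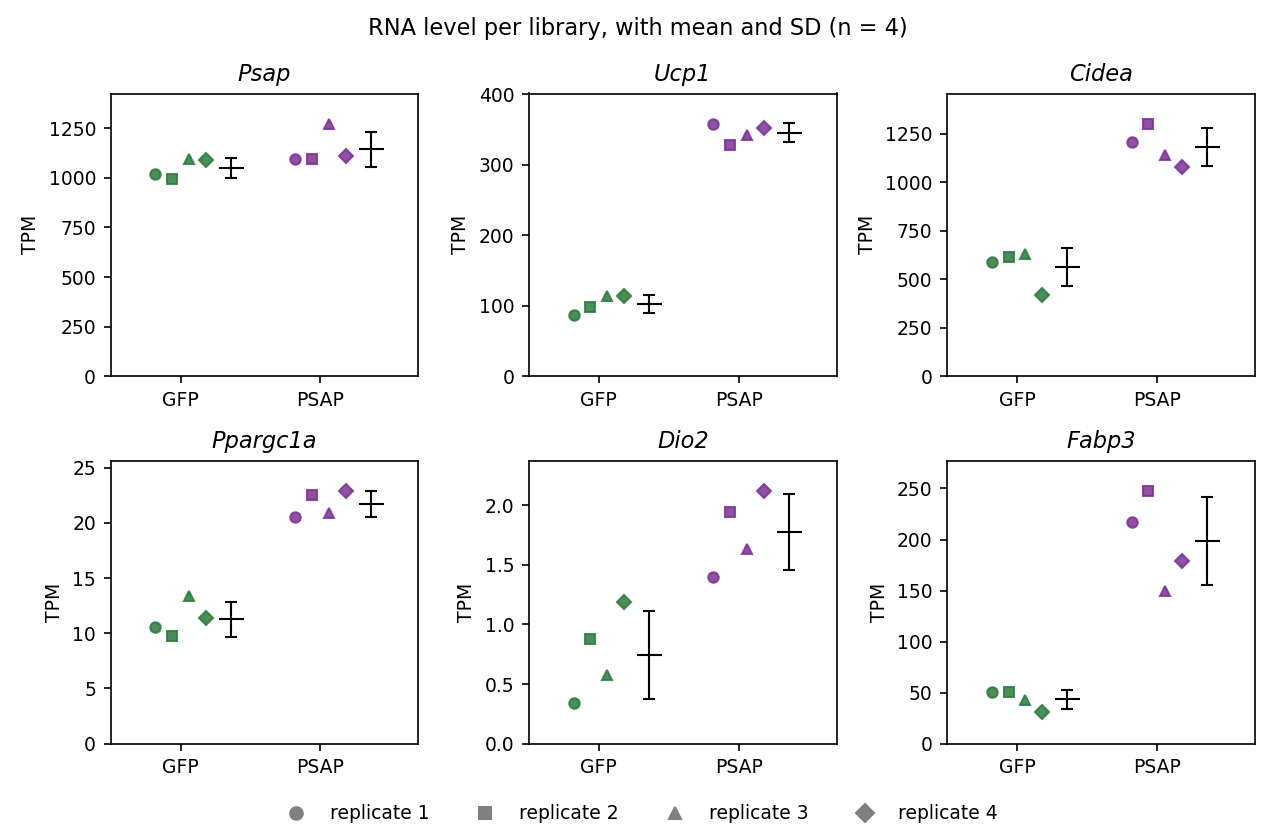
Each panel shows the TPM of a gene (vertical axis, from 0) in the 4 GFP and the 4 PSAP libraries, with a marker shape per replicate number and the mean with its SD in black. Ucp1 lies between 86.8 and 113 TPM in the GFP libraries and between 328 and 358 TPM in the PSAP libraries, whereas the 2 groups nearly touch for Psap.

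The PSAP libraries held more RNA of heat-producing fat cell genes, such as Ucp1, and less RNA of inflammatory genes, such as Saa3. Ucp1, the uncoupling protein of brown and beige fat, rose from 103 ± 12.8 to 345 ± 13.3 TPM (SD, n = 4), a 3.35-fold difference. Saa3, an acute-phase serum amyloid, fell from 6737 ± 2728 to 218 ± 351 TPM (SD, n = 4), with 741 TPM in PSAP replicate 1 and a mean of 43.3 TPM in the other PSAP libraries. Genes of fat oxidation, respiration and cholesterol synthesis were mostly higher, and interferon and lysosomal genes mostly lower, as the list counts below give. In all, 6808 of 11984 genes passed at an adjusted p under 0.05 (limma), which is 56.8%, with 2987 higher and 3821 lower in PSAP. A fold of at least 1.5 was reached by 1976 of them (789 higher, 1187 lower), and a fold of at least 2 by 645 (190 higher, 455 lower). In 6208 genes, or 51.8%, all libraries of one group lay above all of the other, against 2.86% by chance. The split of directions moved with the scaling, to 3574 higher and 3516 lower with median-of-ratios and to 3858 higher and 3239 lower with quantile scaling.

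The 12 largest rises began with Nov, Ptn and Igfbp5. Nov, a matricellular protein of the CCN family, rose from 1.99 ± 0.701 to 36.8 ± 10.1 TPM, with a log2 difference of 3.66 ± 0.20 (SE). Ptn, the growth factor pleiotrophin (chromosome 6, 36714929 to 36810220), rose by 3.11 ± 0.33, and Igfbp5, an insulin-like growth factor binding protein, by 2.62 ± 0.11. Clec3b rose by 2.54, Lrrc17 by 2.51, Mest by 2.35, Itgbl1 by 2.30, and Eln, which encodes elastin, by 2.21. Fabp3, a fatty acid binding protein of muscle and brown fat, rose from 43.4 ± 9.32 to 198 ± 42.8 TPM. Fbn2, the fibrillin of developing microfibrils, the imprinted non-coding RNA H19 (chromosome 7, 142575529 to 142578143) and the collagen gene Col11a1 completed the set, with log2 differences of 2.16, 2.15 and 1.97. The adjusted p of these 12 genes lay between 1.31e-07 and 2.20e-05.

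The 12 largest falls began with Saa3, Nos2 and Mmp3. Saa3 (chromosome 7, 46711998 to 46715700) had a log2 difference of -6.56 ± 1.00 (SE) and an adjusted p of 2.64e-04; for the gene Saa3 it was -7.71 without PSAP replicate 1 and -5.77 without PSAP replicate 3. Nos2, the inducible nitric oxide synthase, fell from 170 ± 43.5 to 3.56 ± 4.97 TPM, with 11.0 TPM in PSAP replicate 1 and at most 1.41 TPM in the other PSAP libraries; the log2 difference of the gene Nos2 was -5.70, and -6.34 without PSAP replicate 1. Mmp3, which encodes stromelysin, fell from 607 ± 197 to 15.9 ± 7.98 TPM, and Lcn2, the iron-carrier binding lipocalin, from 535 ± 138 to 16.3 ± 6.60 TPM. Serpinb2 had a log2 difference of -4.93, Ifi44 of -4.76, Irf7 of -4.67, the complement factor gene Cfb of -4.01 and the chemokine gene Ccl8 of -3.82. Hp, which encodes haptoglobin, fell from 5966 ± 548 to 444 ± 81.5 TPM. The nucleic acid sensor gene Zbp1 had -3.75 and Ifit3 -3.63, the latter shared in part with its near-identical copy Ifit3b.

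Of the thermogenic list, 17 of 22 tested genes rose, 4 fell and 1 did not pass; adjusted over the list alone, 17 rose and 5 fell. Its median log2 difference was 0.73 and its camera adjusted p 1.34e-04, against an adjusted p of 0.290 with an estimated correlation. Ucp1 (chromosome 8, 83290352 to 83298452) had a log2 difference of 1.74 ± 0.08 (SE) with an adjusted p of 1.95e-07, and the exact permutation test gave p = 0.0286. Ppara, a nuclear receptor for fatty acids, rose by 1.41 ± 0.07 and Pank1, an enzyme of coenzyme A synthesis, by 1.24 ± 0.08. Cidea, a lipid droplet protein of brown fat, went from 563 ± 97.8 to 1181 ± 96.0 TPM, and Ppargc1a, a coactivator of mitochondrial biogenesis, from 11.3 ± 1.57 to 21.7 ± 1.16 TPM. Dio2, the deiodinase that activates thyroid hormone, was low, at 0.747 ± 0.369 and 1.77 ± 0.320 TPM, with an adjusted p of 0.00324; in replicates 3 and 4 alone, the gene Dio2 had an adjusted p of 0.0501. The member with the smallest p moved the other way: Tnfrsf9, a beige fat marker that is also an NF-kB-regulated receptor of immune cells, fell from 48.2 ± 1.62 to 3.83 ± 0.474 TPM. The other falling members, chosen after their values were seen, were Pdk4 at -0.98, Fgf21 at -0.98 and Adrb3, the β3-adrenergic receptor, at -0.53.

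Mature fat cell markers and genes of fat synthesis were higher in most cases. In the mature adipocyte list, 14 of 19 genes rose, 1 fell and 4 did not pass, the same counts as adjusted over the list alone, with a median of 0.41 and an adjusted p of 3.11e-05 (0.290 with an estimated correlation). Gpd1, which makes glycerol phosphate, rose from 941 ± 143 to 2182 ± 199 TPM, and Slc2a4, the insulin-responsive glucose transporter, from 102 ± 8.45 to 164 ± 6.27 TPM. Pparg had a log2 difference of 0.00 ± 0.07 and Fabp4 of 0.14 ± 0.15, neither passing; both were chosen after their values were seen. In the lipogenesis list, 11 of 17 rose, 1 fell and 5 did not pass, also adjusted over the list alone, with a median of 0.45 and an adjusted p of 1.69e-04 (0.400 with an estimated correlation). Elovl6, a fatty acid elongase, rose by 1.44 ± 0.08 and Thrsp by 1.27 ± 0.09. The member that fell was Mlxipl, the glucose-sensing regulator ChREBP, at -0.70 and chosen after its values were seen.

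Oxidation, respiration and sterol genes followed the same direction. In the list of lipolysis and fatty acid oxidation, 19 of 22 rose, 1 fell and 2 did not pass, also adjusted over the list alone, with a median of 0.43 and an adjusted p of 1.56e-06 (0.324 with an estimated correlation). Etfdh rose from 299 ± 17.0 to 473 ± 2.95 TPM and Acadm, the medium-chain acyl-CoA dehydrogenase, from 802 ± 54.0 to 1346 ± 28.9 TPM, while the triglyceride lipase gene Pnpla2, chosen after its values were seen, fell by 0.32. In the oxidative phosphorylation list, 24 of 33 rose, none fell and 9 did not pass (25 rose adjusted over the list alone). Its median was 0.31 and its adjusted p 9.36e-08, against an adjusted p of 0.324 with an estimated correlation. Cycs, which encodes cytochrome c, rose by 0.75 ± 0.06 and Sdhd, a subunit of succinate dehydrogenase, by 0.68 ± 0.07. In the cholesterol synthesis list, 18 of 22 rose, 1 fell and 3 did not pass, also adjusted over the list alone, with a median of 0.59 and an adjusted p of 5.17e-07 (0.324 with an estimated correlation). Nsdhl rose by 0.84 ± 0.06 and Idi1 by 1.15 ± 0.09, while Fdft1, chosen after its values were seen, fell by 0.36. The list of creatine and calcium cycling was split, with 4 of 6 genes higher and 2 lower, also adjusted over the list alone, and an adjusted p of 0.601; its median of 0.32 and its mean of -0.04 differ in sign. The creatine transporter gene Slc6a8 fell by 0.50 on the log2 scale, and Alpl, a phosphatase, fell from 5.80 ± 1.81 to 1.80 ± 0.254 TPM.

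**Figure D2:**
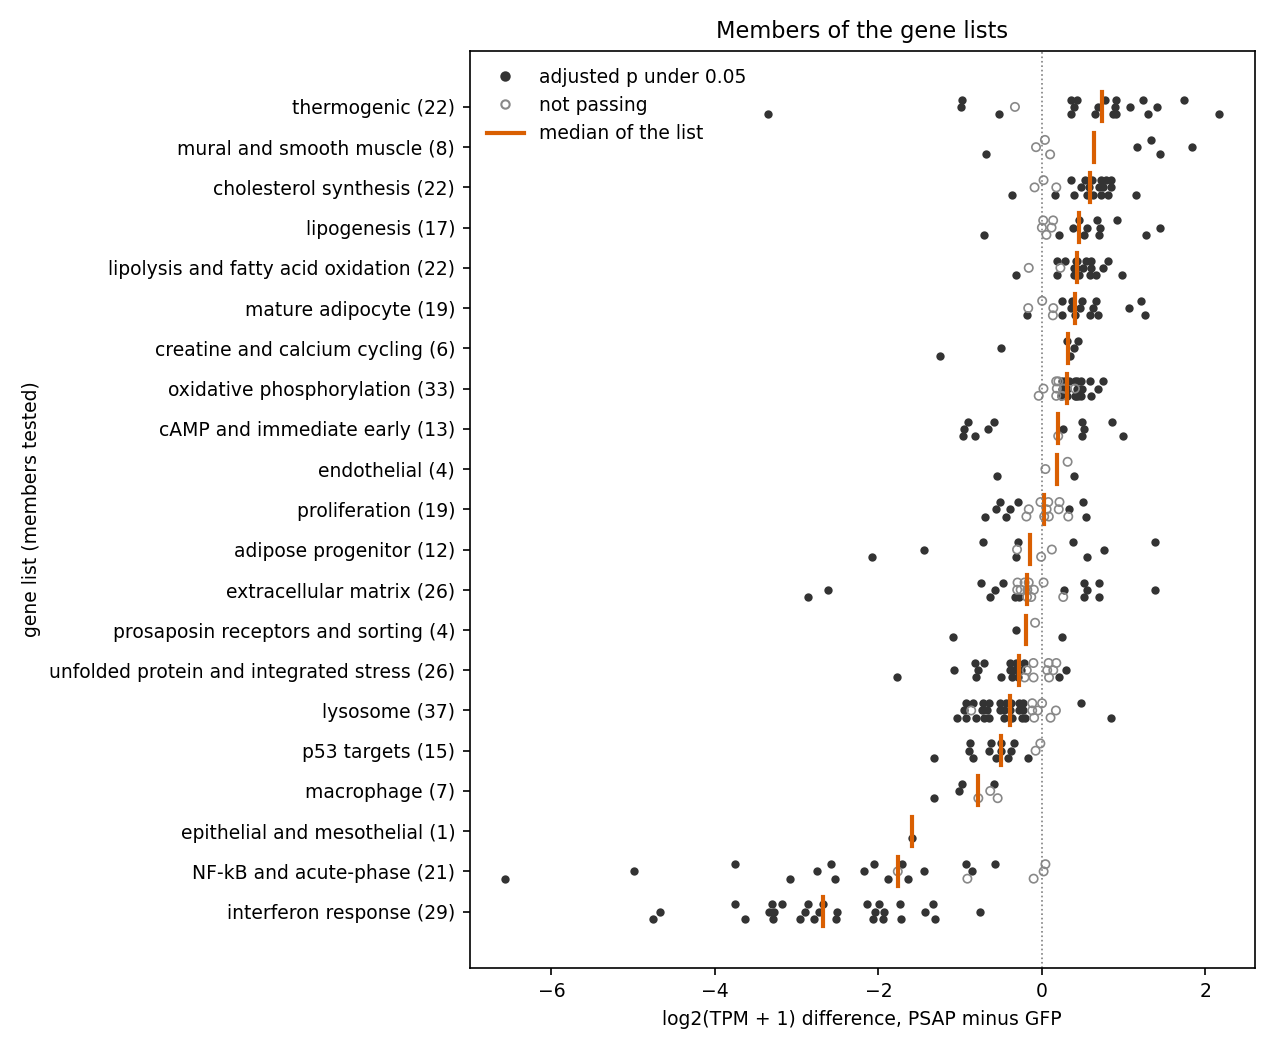
Each point is a tested gene, placed by its log2(TPM + 1) difference between PSAP and GFP libraries (horizontal axis), with a line per gene list on the vertical axis and the number of members tested. Filled points passed at an adjusted p under 0.05, open points did not, and bars mark list medians, which run from -2.67 for interferon response to 0.73 for the thermogenic list.

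All 29 tested genes of the interferon response list fell, over all genes and adjusted over the list alone, with a median log2 difference of -2.67 and a range from -4.76 to -0.76. The adjusted p was 1.75e-12, and 0.324 with an estimated correlation. Irf7, the regulator that amplifies interferon production, fell from 205 ± 95.8 to 6.91 ± 2.86 TPM, Rtp4 from 97.5 ± 28.5 to 9.01 ± 2.81 TPM, and Psmb8, a subunit of the immunoproteasome, from 83.4 ± 25.5 to 11.0 ± 2.39 TPM. In the list of NF-kB and acute-phase genes, 16 of 21 fell, none rose and 5 did not pass (17 fell adjusted over the list alone), with a median of -1.76 and an adjusted p of 4.10e-05 (0.473 with an estimated correlation). Hp and Lcn2 had the smallest p, followed by Relb, an NF-kB subunit, at -1.64 ± 0.13 and the complement gene C3 at -2.53 ± 0.21. PSAP replicate 1 stood apart on this list, with a score of 0.23 against -1.12, -1.59 and -1.54 in the other PSAP libraries; without it, 18 of 21 genes fell, with a median of -2.51. In replicates 1 and 2 alone, 8 of 21 fell, with a median of -0.74 and an adjusted p of 0.0175, and in replicates 3 and 4 alone 18 fell, with a median of -2.83. Without PSAP replicate 1 the list's adjusted p was 1.22e-10, in a range over left-out libraries of 1.22e-10 to 2.38e-04. Of 7 macrophage genes measured alongside these lists, 4 fell and 3 did not pass, also adjusted over the list alone. That list had a median of -0.78 and an adjusted p of 0.0839 (0.586 with an estimated correlation). The adjusted p became 0.0158 without GFP replicate 3, in a range over left-out libraries of 0.0158 to 0.152. Without GFP replicate 3 all 7 fell, and without GFP replicate 4 the median was -0.43; it was -0.41 with a pseudocount of 5 and -0.33 over the 14 members with no filter. Its score was 1.21 in GFP replicate 4 and between -0.24 and 0.48 in the other GFP libraries. Cd68, a lysosomal protein of macrophages, fell from 11.6 ± 3.37 to 4.02 ± 1.16 TPM, and Cd14 from 2.93 ± 1.33 to 0.907 ± 0.468 TPM.

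**Figure D3:**
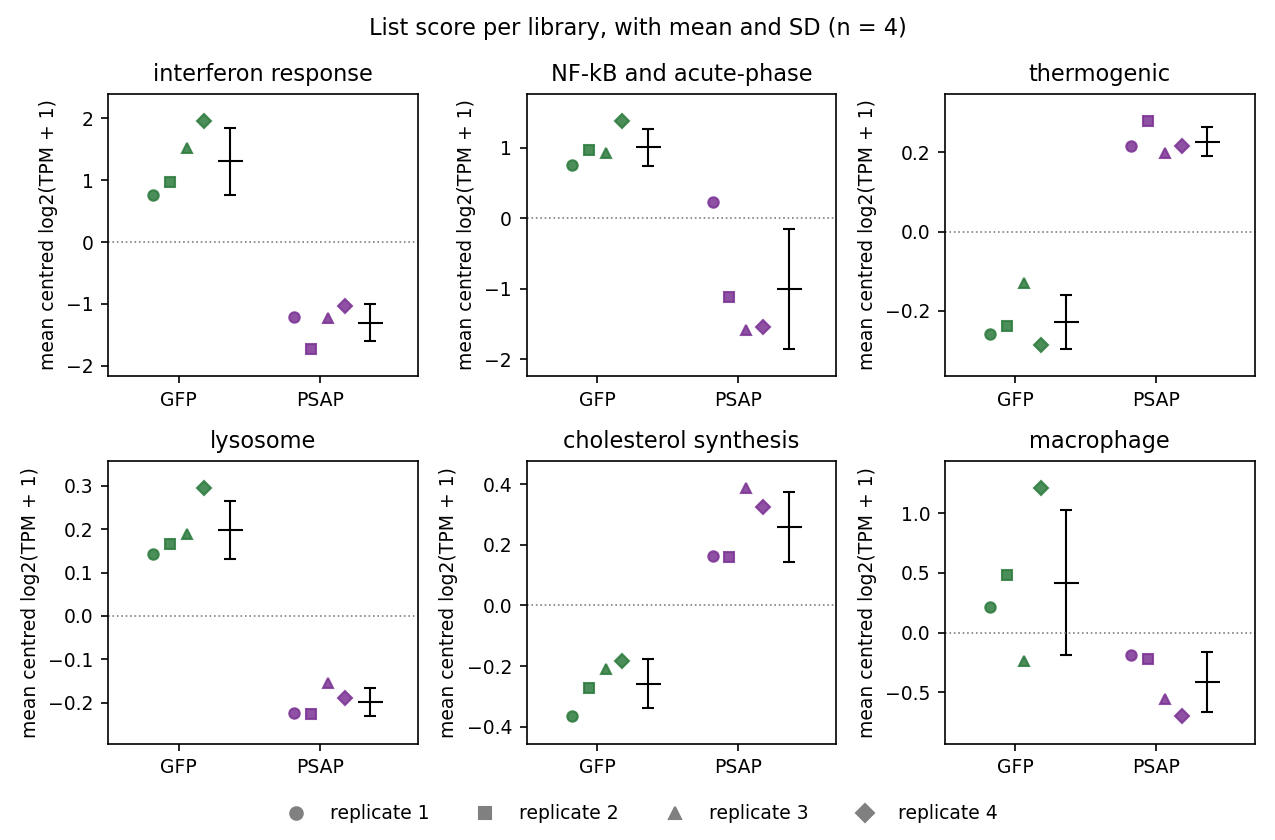
Each panel shows the score of a gene list (vertical axis, mean of centred log2(TPM + 1) over its members) in the 4 GFP and the 4 PSAP libraries, with a marker shape per replicate number and the mean with its SD in black. NF-kB and acute-phase genes score 0.23 in PSAP replicate 1 and between -1.59 and -1.12 in the other PSAP libraries, while interferon scores lie between -1.72 and -1.04 in all PSAP libraries.

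Genes of the lysosome, where prosaposin is processed, were mostly lower: 27 of 37 fell, 2 rose and 8 did not pass (28 fell adjusted over the list alone). The median was -0.39 and the adjusted p 4.20e-06, or 0.324 with an estimated correlation. Gm2a, the activator of ganglioside breakdown, fell from 121 ± 2.06 to 68.5 ± 0.727 TPM, Cd63 from 607 ± 38.8 to 318 ± 13.3 TPM and the cathepsin gene Ctsl from 362 ± 33.5 to 186 ± 5.59 TPM. Galc, whose enzyme galactosylceramidase works with a saposin, rose by 0.84 ± 0.06 on the log2 scale. The other member that rose was Tfeb, a regulator of lysosomal genes, at 0.48 and chosen after its values were seen. Of 4 tested genes for prosaposin receptors and sorting, Lrp1, an endocytic receptor, fell from 347 ± 23.6 to 164 ± 16.8 TPM, Igf2r fell by 0.32, Sort1 rose by 0.24 and M6pr had a log2 difference of -0.08 ± 0.05 that did not pass. The counts were the same adjusted over the list alone, and the adjusted p was 0.358. The receptor genes Gpr37 and Gpr37l1 were under the filter, at 0.0419 TPM or less for Gpr37 and listed at 0 for Gpr37l1.

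Most p53 targets and the larger part of the stress genes were lower. In the list of unfolded protein and integrated stress genes, 15 of 26 fell, 2 rose and 9 did not pass, also adjusted over the list alone, with a median of -0.27 and an adjusted p of 0.01005 (0.324 with an estimated correlation). Of the members with the smallest p, 3 encode transcription regulators: Nupr1 fell from 1543 ± 129 to 450 ± 27.2 TPM, Xbp1 by 0.71 and Ddit3, which encodes CHOP, by 1.08. The chaperone gene Hspa5, chosen after its values were seen, had a log2 difference of -0.18 ± 0.10 that did not pass. Among p53 targets, 13 of 15 fell and 2 did not pass, also adjusted over the list alone, with a median of -0.50 and an adjusted p of 5.47e-05 (0.290 with an estimated correlation). Gdf15, a stress-induced secreted factor, fell from 18.2 ± 1.96 to 6.70 ± 0.758 TPM and the cell cycle inhibitor gene Cdkn1a from 321 ± 27.0 to 179 ± 9.93 TPM. Proliferation genes were split, with 3 of 19 higher, 6 lower and 10 not passing (3 higher and 5 lower adjusted over the list alone), a median of 0.03, a mean of -0.05 and an adjusted p of 0.884. That median ranged from -0.03 without GFP replicate 2 to 0.11 without PSAP replicate 1, and was -0.39 over the 5 members left by a filter of 5 TPM. Mcm4, of the replicative helicase, fell by 0.69 and Ccnb1, which encodes cyclin B1, rose by 0.53. The cAMP and immediate early genes went both ways, with 6 of 13 higher, 6 lower and 1 not passing, also adjusted over the list alone; the adjusted p was 0.818, and the median of 0.20 and camera's direction are opposite in sign to the mean of -0.08 and fry's direction. Fos rose by 0.99 ± 0.08 and Egr1 by 0.86 ± 0.08, while Junb fell by 0.96 ± 0.09 and Sik1 by 0.82 ± 0.08.

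Markers of other cell types in the stromal-vascular fraction did not move together. In the mural and smooth muscle list, 4 of 8 genes rose, 1 fell and 3 did not pass, also adjusted over the list alone, with a median of 0.63 and an adjusted p of 0.0461 (0.324 with an estimated correlation). Without GFP replicate 3, PSAP replicate 1 or PSAP replicate 3 that adjusted p was 0.0526, 0.0511 or 0.0543. The median was 0.07 over the 10 members kept by a filter of 0.1 TPM or by none, and 0.30 with a pseudocount of 5. Smooth muscle actin, Acta2, rose from 47.7 ± 11.4 to 170 ± 20.4 TPM, Tagln from 82.3 ± 17.6 to 184 ± 19.6 TPM, and Myh11 and Cnn1 by 1.34 and 1.44. In the adipose progenitor list, 4 of 12 rose, 5 fell and 3 did not pass (4 and 6 adjusted over the list alone), with a median of -0.15 and an adjusted p of 0.884. Ly6a, which encodes the surface marker Sca-1 and responds to interferon, fell from 1069 ± 389 to 247 ± 55.3 TPM, and Gdf10 rose from 1.88 ± 0.735 to 6.72 ± 2.82 TPM. The extracellular matrix list was also split, with 7 of 26 higher, 8 lower and 11 not passing, also adjusted over the list alone, a median of -0.18 and an adjusted p of 0.653. With the split of replicates 1 and 2 from replicates 3 and 4 as a covariate, 7 were higher and 12 lower. Dcn, which encodes decorin, fell from 697 ± 103 to 95.6 ± 15.3 TPM and Timp1, an inhibitor of matrix proteases, from 1074 ± 309 to 175 ± 44.3 TPM, while Timp3 rose from 36.5 ± 7.25 to 97.5 ± 24.7 TPM. Of 4 endothelial genes tested, Tek rose by 0.39, Flt1 fell by 0.55 and 2 did not pass (2 rose and 1 fell adjusted over the list alone), with an adjusted p of 0.653. The call of the gene Tek ended without GFP replicate 1, 2 or 3 or PSAP replicate 1, 3 or 4, with an adjusted p between 0.0558 and 0.129. The call of the gene Flt1 ended without GFP replicate 2 or 3 or PSAP replicate 2, 3 or 4, with an adjusted p between 0.0596 and 0.0786. The epithelial and mesothelial list had 1 tested gene, Wt1, which fell from 2.91 ± 0.545 to 0.302 ± 0.119 TPM.

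The authors' deposited table, made from read counts, was set beside the TPM fit. It calls 7669 genes at an adjusted p under 0.05, 3807 higher and 3862 lower in PSAP. Of the 11984 genes present in both, 95.6% have the same sign, and the 6389 genes called by both all have the same sign. The authors' deposited table gives log2 fold changes of 1.79 for Ucp1, 1.11 for Cidea, 0.99 for Ppargc1a and 1.28 for Dio2, and of -4.88 for Saa3 and -3.71 for Hp. For the gene Eln it gives 3.15, against 2.21 in the TPM fit with a pseudocount of 1 and 2.98 with a pseudocount of 0.1. Flt1, called in the TPM fit, is not called there, with an adjusted p of 0.141.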

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

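All tests in the weighing below were chosen only after the results were seen; the search for libraries far from the others of their group was planned. A value is given here where the gap of the highest or lowest library to the nearest of the others, over the whole range of its group on the log2 scale, passed the 95% critical value for 4 libraries. That was so for 7 of 212 groups of values, and chance alone gives about 10.6.

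Psap RNA was little higher in the PSAP libraries, and PSAP replicate 3 lay apart at 1273 TPM against 1095 to 1111 TPM in the others, with a gap of 0.905 of the range. An exchange of some libraries between the groups would leave a library closer to the other group, but the lowest correlation within a group exceeded the highest between groups by 0.0195. A general rise of lysosomal genes would lift the list's median, which was -0.39, and 34 of 37 members lay below Psap. Transgene reads that were not assigned to the mouse gene may leave the log2 difference at 0.12, and this cannot be told apart from a low level of transgene RNA, because the species and form of the transgene are not given in the labels. An exchange of all libraries would leave the correlations as they are, and a Psap log2 difference of 0.12 is too small to decide it, so it cannot be told apart either.

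NF-kB and acute-phase genes stood higher in PSAP replicate 1 than in PSAP replicates 2 to 4, and its Nos2 lay apart at 11.0 TPM against 0.835 to 1.41 TPM, with a gap of 0.854 of the range. On the scale from the mean of the other PSAP libraries to the mean of the GFP libraries, PSAP replicate 1 reached a median of 42.6% over the 16 NF-kB genes called, 15 of which lay above all other PSAP libraries. The quartiles were 15.1% and 100.5%, so the members differed widely. Lcn2, Hp and Saa3 reached only 2.44%, 2.55% and 10.4%. Ccl2, a monocyte chemokine chosen after its values were seen, stood at 436 TPM there, against a mean of 40.1 TPM in the other PSAP libraries and 284 TPM in the GFP libraries. Carry-over of a GFP library may be set against this: it would lift interferon genes by the same share, but their median was 0.290% with an upper quartile of 3.05%. No biological explanation was tested, and a difference in the handling of that library's cells stays open.

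The other values were in the GFP group. In GFP replicate 4, Cidea stood at 419 TPM against 589 to 632 TPM, a gap of 0.830 of the range. Lcn2 stood at 742 TPM in GFP replicate 4 against 461 to 477 TPM, a gap of 0.927. Gdf10 stood at 2.98 TPM in GFP replicate 4 against 1.47 to 1.55 TPM, a gap of 0.930. The score of the unfolded protein and integrated stress list was 0.07 in GFP replicate 4 against 0.19 to 0.20, a gap of 0.881. Idi1 stood at 16.8 TPM in GFP replicate 1 against 20.6 to 21.3 TPM, a gap of 0.857.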

How the results depend on the processing

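The fits on replicates 1 and 2 against replicates 3 and 4, as a covariate or apart, were chosen after the data were seen; the other alternatives were planned. The alternatives were run for 85 of the named genes, with the 3 members of smallest p for each list rather than 4. None of these genes and no list called in either fit turned its direction. The balance of directions did turn, from 2987 higher and 3821 lower to 3574 and 3516 with median-of-ratios and to 3858 and 3239 with quantile scaling, where the median over all genes went from -0.04 to 0.03. The test of 4 uncalled lists turned its direction in 10 list values: proliferation with a filter of 0.1 TPM (adjusted p 0.969), quantile scaling (0.986), replicates 3 and 4 only (0.914), and without PSAP replicate 1 or 2; adipose progenitor with the replicate block (0.984) and without GFP replicate 4 or PSAP replicate 2; endothelial with replicates 3 and 4 only (0.930); and cAMP and immediate early with fry (0.729). Without each library the adjusted p ranged from 0.718 to 0.9996 for proliferation and from 0.718 to 0.938 for adipose progenitor. With a filter of 5 TPM the median of the cAMP list was -0.16 and that of proliferation -0.39, over 10 and 5 genes. Of the named genes checked other than Psap, and of the list tests, 1908 gene values and 460 list values kept their direction and side of the threshold. A further 24 gene values and 23 list values lost the call, and 10 and 5 gained it. A count moved by more than 1.5 times with a fold of at least 1.5 (1976 genes, 789 higher and 1187 lower) and with replicates 3 and 4 only (4344 genes, 1891 higher and 2453 lower). A minimum fold lowers the count by construction; replicates 1 and 2 only, as many libraries as replicates 3 and 4, gave 6362 genes. Without each library in turn, 5888 to 6654 genes passed, 2513 to 3095 higher and 3375 to 3783 lower. Psap ranged from 0.07 to 0.14 without each library and passed with median-of-ratios scaling (0.17) and with the replicate block (0.12, adjusted p 0.0424); it has no value in TPM rescaled without Psap. The mural list lost its call with a filter of 0.1 TPM (0.114), no filter (0.121), median-of-ratios (0.0752), quantile scaling (0.0701), array weights (0.0557), the replicate block (0.0601), the covariate (0.0772) and replicates 1 and 2 only (0.0554), and ranged from 0.0264 to 0.0543 without each library. The macrophage list passed with array weights (0.0491), replicates 3 and 4 only (0.0350) and fry (0.0362), and had 0.586 with an estimated correlation. It ranged from 0.0158 to 0.152 without each library, and has no test with a filter of 5 TPM, which leaves too few members. The prosaposin receptor and sorting list passed with fry (7.18e-04) and had 0.586 with an estimated correlation. None of the 12 list calls held with an estimated correlation, and all did with fry. The former gave an adjusted p of 0.290 for the thermogenic, mature adipocyte and p53 lists, 0.400 for lipogenesis and 0.473 for NF-kB. It gave 0.324 for the fatty acid oxidation, oxidative phosphorylation, cholesterol, lysosome, interferon, unfolded protein and mural lists. Apart from the minimum fold, the cause was not tested. Replicate numbers were not taken as pairs. After removing group means, same-numbered libraries correlated over genes at -0.00, 0.23, 0.31 and 0.32. The GFP and PSAP libraries numbered 3 were each other's best match, as were those numbered 4, but not those numbered 1 or 2. With the number as a block, 7654 genes passed (3414 higher, 4240 lower), 6776 of them shared with the fit without it, and 8 matrix genes were higher and 13 lower. The gene Sort1 lost its call with replicates 3 and 4 only (adjusted p 0.0729), and the gene Cd14 with replicates 1 and 2 only (0.136). Without single libraries some small list counts and medians moved: 2 oxidation genes fell without GFP replicate 1, 2 mature adipocyte genes fell without PSAP replicate 3 and none without PSAP replicate 4, 1 unfolded protein gene rose without GFP replicate 2 or PSAP replicate 4, and without GFP replicate 4 the matrix and progenitor medians were -0.08 and -0.04. Without PSAP replicate 2 the matrix and progenitor medians were -0.12 and -0.08. Read depth is unknown, so what it limits cannot be given.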

Other observations

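The 7 gene lists below, and every test in this part except the splits of the libraries, were chosen only after the results were seen. The adjusted p of these lists, taken over the 7 alone, therefore describes values already seen and is no independent test. Genes that prompted a list were left out only in a second test of the imprinted and the metalloproteinase list. Genes of antigen presentation by MHC class I fell: 14 of 15 were lower and 1 did not pass, with a median log2 difference of -1.83 and an adjusted p of 3.87e-08 (0.284 with an estimated correlation). H2-K1, a class I heavy chain that shares reads with its relatives, fell from 1273 ± 237 to 334 ± 9.64 TPM, and B2m, its light chain, from 5011 ± 1018 to 1394 ± 77.6 TPM. Psmb8 is also in the interferon list. Among metallothioneins and iron genes, 7 of 9 fell, 1 rose and 1 did not pass, with a median of -0.68 and an adjusted p of 0.00419 (0.284 with an estimated correlation). Mt2 fell from 6255 ± 1735 to 1549 ± 405 TPM and the haem oxygenase gene Hmox1 from 3115 ± 174 to 905 ± 108 TPM, while the transferrin receptor gene Tfrc rose from 60.0 ± 11.9 to 95.2 ± 11.9 TPM.

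Of the tricarboxylic acid cycle genes, 16 of 18 rose, Suclg2 fell by 0.14 and 1 did not pass, with a median of 0.43 and an adjusted p of 5.38e-07 (0.284 with an estimated correlation). Ogdh, of the oxoglutarate dehydrogenase complex, rose from 148 ± 18.6 to 337 ± 25.9 TPM and Idh3a from 837 ± 101 to 1429 ± 65.4 TPM. In the breakdown of branched-chain amino acids, 8 of 19 rose, none fell and 11 did not pass, with a median of 0.14 and an adjusted p of 0.0109 (0.428 with an estimated correlation). Dld, which rose by 0.62, is counted in both lists, and Sdha and Sdhb of the cycle are also in the oxidative phosphorylation list. Elastic fibre genes were split, with 5 of 18 higher, 7 lower and 6 not passing and an adjusted p of 0.500; Eln and Fbn2 rose, while Emilin1 fell from 97.0 ± 10.1 to 39.2 ± 6.30 TPM.

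Interferon and NF-kB genes were lower and thermogenic genes higher in the same libraries. A larger share of adipocytes may raise thermogenic genes. Of 22 tested, 12 lay over 2 SE above the mature adipocyte median of 0.41 and 5 below it. Mature adipocyte markers also lay far from that median, such as Gpd1 at 1.22 ± 0.11 (SE) and Pparg at 0.00 ± 0.07. Of the other cell types, 4 of 8 mural genes rose and 1 fell, while 4 of 7 macrophage genes fell and none rose. These values therefore cannot decide whether a larger share of adipocytes accounts for the rise. A graded dependence of thermogenic genes on the interferon level gave a pooled slope within the groups of -0.0217 (-0.0619 to 0.0457 without each library; exact permutation p = 0.825 over 576 arrangements), against -0.175 between the groups, and 4 libraries a group cannot exclude it. Virus preparations or doses may differ in the innate response they evoke, and the interferon median was -2.67. This cannot be told apart from an effect of PSAP, because virus and transgene differ together between the groups. No culture without virus is among the samples. An action of PSAP itself stays among the open explanations.

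The rise of H19, Mest and Peg10 raised the hypothesis that imprinted genes rise as a set. Without these 3, the imprinted list had 6 of 11 genes higher and 1 lower, with a median of 0.21. Its adjusted p was 0.0445 (0.459 with an estimated correlation), so the call holds only with the preset correlation. It also depends on the choice of the 7 lists, because the small p of some of the others lowers the adjusted p of this one. With H19, Mest and Peg10, 9 of 14 rose, 1 fell and 4 did not pass, with an adjusted p of 0.00163 (0.284 with an estimated correlation). That list holds the genes that prompted the test. The fall of Mmp3 raised the hypothesis that matrix metalloproteinases fall as a set. Without Mmp3, 6 of 10 fell and 2 rose, with a median of -0.61 and a camera adjusted p of 0.0682 (0.459 with an estimated correlation). With Mmp3, which prompted the test, 7 of 11 fell, 2 rose and 2 did not pass. The camera adjusted p was then 0.0215 (0.423 with an estimated correlation).

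Of the 35 splits of the 8 libraries into 4 and 4, the real one alone gave as many genes. That is a share of 1 in 35, the smallest that these splits can give. It was the same for all 6808 genes, for the 2987 higher and for the 3821 lower. The highest of the other splits gave 1 gene. Every other split mixes the groups, so the group difference adds to its spread and keeps its count low. The splits also take the libraries as exchangeable. Replicates 1 and 2, however, lay apart from replicates 3 and 4 in both groups on the second principal component. No label says whether the libraries are separate cultures. A difference between cultures or batches is therefore not excluded.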
